A study of Homo sapiens with 4 samples.

How the data were processed

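Gene expression was measured on Illumina bead arrays in H9 cells, an established line of human embryonic stem cells. The 4 arrays held 2 samples taken before gamma irradiation (0 h) and 2 taken 24 h after it, and each group came from the time point and source stated in the labels. Per the labels' protocols, total RNA was extracted with a column kit and amplified into biotin-labelled cRNA before hybridisation. The labels do not say whether the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical. The labels give no radiation dose, and the series' title speaks of a low dose. No sample of unirradiated cells at 24 h was analysed here. All 4 arrays lay on 1 slide, and the positions on it differed between the groups, so position and group cannot be told apart.

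Per the file headers, the deposited table of non-normalized values holds for each array a mean bead intensity per probe on a linear scale and a detection p-value per probe. The authors' processed table holds log2 values, and limma is named as the tool per the submitters' processing notes, with the version and steps not given in the sources used here. Set against neqc of the same array's signals, each column of the authors' log2 table had a correlation across probes of 0.99998 and differed by at most 0.0563, with medians of 5.35 to 5.36. The scale was therefore taken as log2 after background correction and quantile normalization, without centring of genes. The authors' table holds 34466 of the 47217 probes, and the rule that chose them stays unknown.

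The intensities were background-corrected and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), which fitted the background from the deposited detection p-values and added an offset of 16. Raw array medians were 158.4 and 175.2 at 0 h and 143.8 and 134.7 at 24 h. Between 19705 and 20443 probes per array had a detection p under 0.05. The bright end of the signal, its 99th percentile over the median of undetected probes, was 82 and 83.1 at 0 h and 69.7 and 60.4 at 24 h. For arrays, their number limits the precision, and here that number was 2 per group.

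A probe was kept when its detection p was under 0.05 on at least 2 of the 4 arrays, which left 20361 probes. Gene names came from the platform annotation, which gives 1 symbol for 26358 probes, several for 3 and none for 20856. Entrez identifiers of 26325 probes were found in the RefSeq annotation of the GRCh38.p14 assembly, and 0 symbols changed. No coordinates are printed, because no genome build is named for the array. Of the kept probes, 14235 had 1 symbol, and the probe with the highest mean log2 signal over all 4 arrays stood for its gene. That left 11030 genes of the 18348 named on the array. Probes without a single symbol entered no gene test.

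Each gene was fitted with lmFit and eBayes of limma, 24 h against 0 h, without a replicate block, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Changes are log2 differences, 24 h minus 0 h, with the standard error (SE) of the fit, and fold changes are on the scale of the background-corrected signals with their offset. A gene not detected on either array of a group has only a bound. The bound divides the bright group's mean by the dim group's mean of, for each array, the higher of the lowest detected signal and the gene's own signal, on normalized log2 values, and is written as at least N-fold. The bound carries no sampling error, so for a gene that did not pass it describes these arrays and shows no change. The eBayes prior carried 2.56 degrees of freedom beside the 2 of the residuals. The median SD within groups was 0.332 in the dimmest 10% of genes and 0.073 in the brightest 10%.

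The lists of genes were written before the data were examined, as were the design, the alternatives and the rule for named genes. They covered p53 targets, DNA damage signalling, 6 kinds of DNA repair, DNA replication, mitosis, histones, apoptosis, pluripotency, markers of neurectoderm, mesoderm, endoderm, trophoblast and fibroblasts or mesenchyme, interferon response, NF-kB, NRF2, ATF4, hypoxia and glycolysis, cholesterol synthesis, heat shock and the unfolded protein response, and immediate early genes. Of the 26 lists, the 24 with at least 5 measured members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists. Camera with the correlation estimated per list and fry, a rotation test of whether a list's genes move one way on balance, stood beside it. With an estimated correlation, camera rests on the 2 residual degrees of freedom and has little power. A miss there is weak evidence against a shift, and the preset value is an assumption that was not tested. Members were also adjusted over their list alone, by the Benjamini-Hochberg method on the limma p-values of that list. This adjustment takes no account of the other lists or genes, and covers as few as 2 genes for the mesoderm markers. Over all genes, 3345 of 11030 had an unadjusted limma p under 0.05, so counts adjusted over a list alone do not mark that list as changed. The named genes were the 8 largest rises and 8 largest falls among called genes whose 24 h arrays both lay on the same side of both 0 h arrays, leaving out symbols without a proper gene name. The rule added the 3 measured genes of smallest p in each list, and CDKN1A, MDM2, POU5F1, NANOG and PARP1 whatever their p; some further items of the rule are not reported here. Named in these ways were 91 genes, and further genes are given as examples of a list or, where said, chosen after their values were seen.

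The steps were tested on simulated data with 11030 genes, the fitted levels and 200 changed genes for the 24 h against 0 h comparison. With the same variance at every level, the fit recovered 31% of genes changed by 1 on the log2 scale and 88% of those changed by 2, with 3 false calls. With variance that followed the level, it recovered 29% and 84%, with 6 false calls. Variances came from the fitted priors, genes were drawn as independent, and no effect was shared by an array. Fewer genes were changed than the 3345 with an unadjusted limma p under 0.05 in the data, so these shares need not hold there. Alternatives tried were another background correction, none, scaling to the 75th percentile, the authors' log2 values, no detection filter, a stricter filter (p under 0.01 on all 4 arrays), the mean of a gene's probes, every probe on its own, an eBayes prior that follows the level and resists outliers, a replicate block, each array left out, and a minimum of 1.5-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.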

Results

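The arrays measured transcripts of H9 human embryonic stem cells before gamma irradiation (0 h, n = 2) and 24 h after it (n = 2). Of 47217 probes, 19705 to 20443 were detected on an array, and 11030 named genes were tested. Across genes, Pearson's r was 0.9913 between the 0 h arrays, 0.9875 between the 24 h arrays and 0.9711 to 0.9794 between the groups; genes are not independent replicates. The comparison asks which transcripts of pluripotent cells differ a day after irradiation, in a series concerned with irradiation and gene targeting.

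GDF15, a secreted stress cytokine and p53 target, rose most of all called genes, 5.64-fold (log2 change 2.50 ± 0.15 SE, adjusted p = 0.0447, limma). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 4.12-fold (2.04 ± 0.10), and SUN2, a protein of the nuclear envelope, rose 3.47-fold (1.79 ± 0.19). ST3GAL2, a sialyltransferase, rose 3.38-fold, ALDH1A3, an enzyme of retinoic acid synthesis, rose 3.26-fold, and FOSL1, an AP-1 transcription factor, rose 3.11-fold. FOXJ1, the master regulator of motile cilia, and the antisense transcript SERTAD4-AS1 were not well above background at 0 h, and rose at least 2.76-fold and at least 2.995-fold. In the other direction, LANCL2 fell 3.82-fold (log2 change -1.93 ± 0.12), LZTFL1, a regulator of ciliary traffic, fell 3.56-fold, MAGOHB, a component of the exon junction complex, fell 3.08-fold, and CUZD1 fell 2.94-fold.

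The lymphoid transcription factor SPIB fell 4.28-fold, SLC35G1 3.56-fold and JAKMIP2 2.95-fold, each detected on both 0 h arrays and on 1 of the 2 arrays at 24 h. ANK2, which encodes the membrane adaptor ankyrin-B, was not well above background at 24 h and fell at least 3.39-fold. Adjusted p for these 16 genes was 0.0447 to 0.0496, and their 24 h arrays lay on the same side of both 0 h arrays. Fold sizes, bounds included, depend on the background correction: without it, the log2 change was 1.74 for GDF15, 1.26 for ANGPTL4 and -0.92 for SPIB, and 14 of the 34 named genes that were called had folds over 1.5 times smaller, all still called. With the mean of its probes, the change of ANGPTL4 was 1.32.

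**Figure D1:**
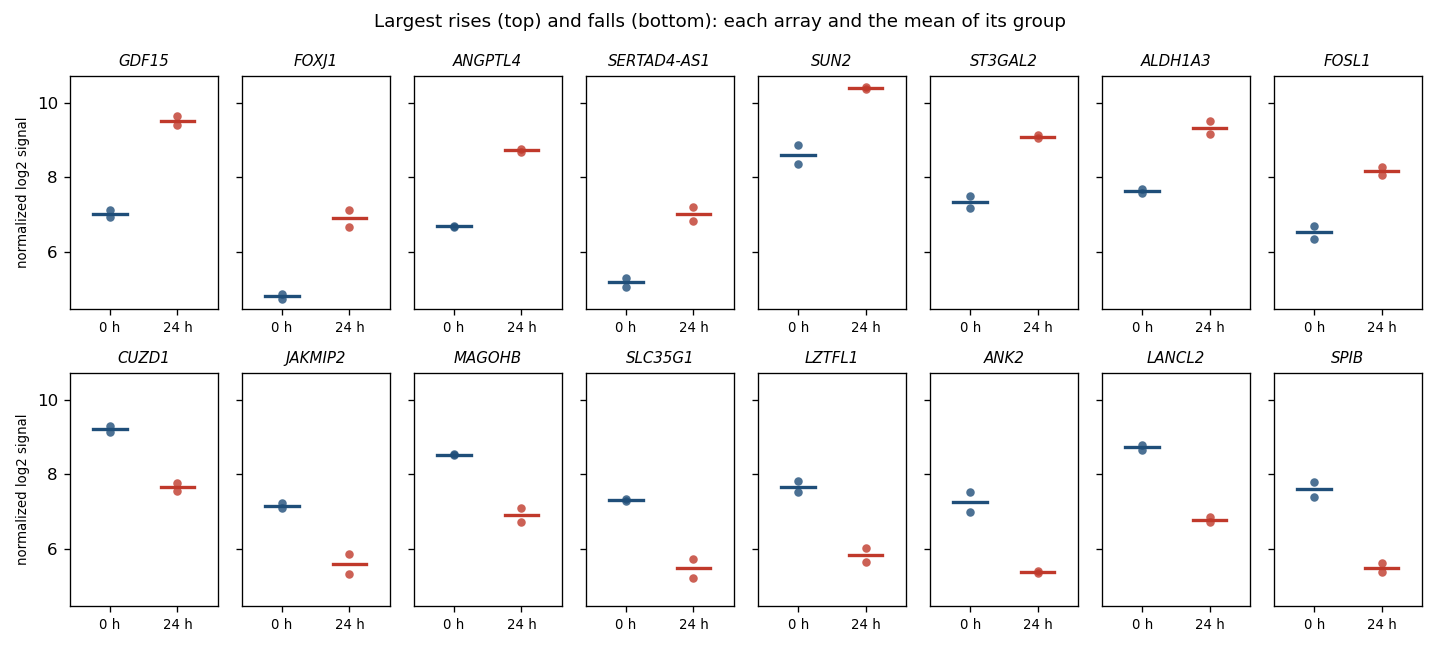
Normalized log2 signal (y axis) of the 8 genes that rose most and the 8 that fell most, at 0 h and 24 h (x axis); points are single arrays and lines are means of 2 arrays. GDF15 stood at 7.13 and 6.92 at 0 h and at 9.65 and 9.39 at 24 h, and in each panel both 24 h points lie on 1 side of both 0 h points.

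In all, 251 genes passed adjusted p of 0.05, 149 higher and 102 lower at 24 h, with a median change of 2.06-fold and none under 1.67-fold. Of these, 200 were measured in both groups, 27 were not well above background at 0 h and 24 at 24 h. At an unadjusted p under 0.05 there were 3345 genes, 1655 higher and 1690 lower, against 552 by chance. The groups did not overlap for 6791 genes (61.6%), against 33.3% by chance with 2 arrays per group. Adjusted p clustered just under the threshold, with 0.0447 the smallest. With any single array left out limma called 0 genes, with 1831 to 3341 at an unadjusted p under 0.05. The share of called genes that were higher was 59.4%, and 49.8% (359 higher, 362 lower) after scaling to the 75th percentile in place of quantile normalization. With that scaling, 294 of 438 dimmer called genes and 65 of 283 brighter ones were higher.

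The p53 target list was shifted higher at 24 h, with 41 of 49 measured members above 0 and a median log2 change of 0.42 (camera adjusted p = 5.61e-07; adjusted p = 0.44 with an estimated correlation; fry adjusted p = 0.0355). GDF15, PRDM1, ZMAT3, DDB2 and PHLDA3 rose, and 44 members did not pass over all genes tested. Adjusted over the list alone, 20 were higher and 1 was lower. The 8 members below 0 included PTP4A1 (-0.51 ± 0.11), PPM1D (-0.23 ± 0.11) and CCNG1 (-0.05 ± 0.15). ZMAT3, an RNA-binding protein, rose by 1.29 ± 0.14 on the log2 scale, DDB2, which recognises ultraviolet lesions for excision repair, by 1.13 ± 0.13, and PHLDA3, an inhibitor of AKT, by 1.04 ± 0.12. The transcriptional repressor PRDM1 was not well above background at 0 h and rose at least 1.78-fold. Members that missed the threshold included SPATA18 (1.02 ± 0.15, adjusted p = 0.0505), GADD45A (1.00 ± 0.19, adjusted p = 0.0614), RRM2B (0.90 ± 0.14, adjusted p = 0.0525) and the pro-apoptotic PMAIP1 (0.83 ± 0.12, adjusted p = 0.0516).

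The cell cycle inhibitor CDKN1A was named by 1 probe, which was not detected on any of the 4 arrays (lowest detection p 0.329). This leaves its expression open, since the probe may miss the transcript. The p53 ubiquitin ligase MDM2 was named by 2 probes, detected on 1 and 0 arrays. Neither was tested, and PARP1 was not analysed here.

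Camera, which looks for members that move one way, called none of the DNA repair and damage signalling lists. The fry test for changes in either direction called 21 of all 24 lists, so it singles out none. In the main fit DDB2 was the sole member of these lists that passed. Other processing called more of them, such as TIPIN under 7 of 15 alternatives, and UNG and TP53BP1 under 6 each. In homologous recombination 0 of 22 genes passed (camera adjusted p = 0.499; 1 higher adjusted over the list alone), with MRE11, a nuclease of broken ends, at 0.65 ± 0.10 (adjusted p = 0.0525), RAD51C at 0.51 ± 0.10 and DNA2 at -0.45 ± 0.10. In end joining 0 of 12 passed (adjusted p = 0.309; 0 adjusted over the list alone), with RIF1 at -0.40 ± 0.10, POLL at -0.60 ± 0.17 and TP53BP1 at -0.47 ± 0.11. In base excision and PARP genes 0 of 20 passed (adjusted p = 0.853; 3 higher and 2 lower adjusted over the list alone), with UNG at -0.54 ± 0.10, MUTYH at 0.58 ± 0.12 and NTHL1 at 0.50 ± 0.11.

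Mismatch repair had 0 of 5 passing and 4 below 0 (adjusted p = 0.19; 2 lower adjusted over the list alone), with PMS1 at -0.58 ± 0.14, MSH6 at -0.46 ± 0.13 and MLH3, detected on 1 of the 2 arrays at 24 h, at -0.44 ± 0.23. In nucleotide excision repair 1 of 19 passed, DDB2 (camera adjusted p = 0.675, and 1 higher adjusted over the list alone). RAD23B stood at -0.58 ± 0.15. ERCC6, not well above background at 24 h, did not pass (limma adjusted p = 0.0662), with a bound of 1.02-fold lower. The Fanconi anemia list had 0 of 11 passing (adjusted p = 0.702; 1 higher and 1 lower adjusted over the list alone), with FANCB at -0.65 ± 0.11, FANCE at 0.59 ± 0.12 and FANCC, detected on 1 of the 2 arrays at 24 h, at -0.89 ± 0.25. In damage signalling 0 of 17 passed (camera adjusted p = 0.66, and 1 lower adjusted over the list alone). TIPIN, a fork protection protein, stood at -0.69 ± 0.10 (limma adjusted p = 0.0516). CLSPN, not well above background at 24 h, did not pass (limma adjusted p = 0.074), with a bound of 1.09-fold lower.

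The DNA replication list was shifted lower, with 26 of 32 measured members below 0 and a median of -0.16 (camera adjusted p = 0.00251; adjusted p = 0.44 with an estimated correlation; fry adjusted p = 0.021). RRM2, a subunit of ribonucleotide reductase, fell by 1.26 ± 0.16 on the log2 scale. CDC6, which loads the replicative helicase, fell by 1.13 ± 0.10, and the other 30 did not pass. At 24 h CDC6 lay near background, at 5.613 and 5.609 against lowest detected signals of 5.509 and 5.471. Its log2 change was -0.427 without background correction, and its SE 0.27 with the trend and robust prior. It stayed called under both. Adjusted over the list alone, 3 were lower. UHRF1, which carries DNA methylation through replication, stood at -0.74 ± 0.13 (adjusted p = 0.0577), and MCM2, a helicase subunit, at -0.48 ± 0.12 (adjusted p = 0.0834).

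Mitosis genes had 24 of 36 above 0, a median of 0.08 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.257). HMMR, a spindle protein, stood at 0.83 ± 0.13 (adjusted p = 0.0519), CDC25B at 0.43 ± 0.10 and KIF2C at 0.42 ± 0.11. Of 13 histone genes, 10 were below 0 and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.173), with H4C3 at -0.40 ± 0.11 and H2BC5 at 0.70 ± 0.18. With the mean of its probes, H2BC5 stood at -0.014 (adjusted p = 0.972, in a range of 0.0292 to 0.972 over all alternatives). H2BC4, not well above background at 24 h, did not pass (limma adjusted p = 0.0795), with a bound of 1.42-fold lower.

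Markers of fibroblasts and mesenchyme were shifted higher, with 10 of 10 measured members above 0 and a median of 0.81 (camera adjusted p = 3.33e-05; adjusted p = 0.44 with an estimated correlation; fry adjusted p = 0.021). The smooth muscle actin ACTA2 rose 2.84-fold (1.504 ± 0.114), the calcium-binding protein S100A4 2.26-fold (1.17 ± 0.10) and the actin-binding TAGLN 1.84-fold (0.88 ± 0.10). The collagen chain COL1A1 rose by 1.05 ± 0.14 on the log2 scale (adjusted p = 0.0498) and the intermediate filament VIM by 0.86 ± 0.12 (adjusted p = 0.0494). Adjusted over the list alone, 8 were higher. COL1A2, the partner chain of COL1A1, stood at 0.33 ± 0.11 (adjusted p = 0.136), and 9 of the 19 named members were not above background on 2 arrays and were not tested.

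Cholesterol synthesis genes were shifted lower, with 13 of 13 measured members below 0 and a median of -0.56 (camera adjusted p = 8.47e-06; adjusted p = 0.456 with an estimated correlation). INSIG1, the sterol-sensing retention factor of SREBP, fell 2.63-fold (-1.39 ± 0.12) and SQLE, squalene epoxidase, fell 2.38-fold (-1.25 ± 0.12). The remaining 11 did not pass over all genes, among them MSMO1 (-0.93 ± 0.13, adjusted p = 0.0505), and adjusted over the list alone 9 were lower.

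Hypoxia and glycolysis genes were shifted higher, with 19 of 23 above 0 and a median of 0.25 (camera adjusted p = 0.00589; adjusted p = 0.456 with an estimated correlation). ADM, the vasoactive peptide adrenomedullin, rose 2.10-fold (1.07 ± 0.11) and BNIP3, a mitophagy receptor, 1.98-fold (0.98 ± 0.10). Adjusted over the list alone, 4 were higher. ANKRD37, a target of hypoxia-inducible factor, stood at 0.73 ± 0.11 (adjusted p = 0.0523), and the glycolytic enzymes GAPDH (0.03 ± 0.10) and LDHA (-0.13 ± 0.12) did not pass.

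Immediate early genes were shifted higher, with 12 of 17 above 0 and a median of 0.29 (camera adjusted p = 0.00581; adjusted p = 0.44 with an estimated correlation). FOSL1 rose, as did the stress-induced IER3 (0.96 ± 0.12) and the AP-1 subunit JUN (0.81 ± 0.10). Adjusted over the list alone, 6 were higher. FOS stood at 1.09 ± 0.16 (adjusted p = 0.0516).

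The interferon response list was called higher, with 15 of 19 above 0 and a median of 0.21 (camera adjusted p = 0.0284; adjusted p = 0.59 with an estimated correlation). ISG15, a ubiquitin-like protein, rose 2.06-fold (1.04 ± 0.11) and was also the sole member past the threshold adjusted over the list alone, with HLA-B at 0.45 ± 0.11 and PSMB9 at 0.38 ± 0.11. The list's adjusted p was 0.0533 with scaling to the 75th percentile, 0.0597 and 0.0707 without 0 h replicate 1 or 2, and 0.167 without 24 h replicate 2, in a range of 0.0169 to 0.59 over all alternatives.

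Heat shock and unfolded protein response genes missed the threshold as a list (13 of 20 below 0, median -0.20, camera adjusted p = 0.0767). The chaperone HSPA1B fell by 0.83 ± 0.11 on the log2 scale, and 6 were lower adjusted over the list alone; HSPH1 stood at -0.70 ± 0.10 (adjusted p = 0.051) and HSPA1A at -0.79 ± 0.12 (adjusted p = 0.0521). In the NRF2 list (camera adjusted p = 0.178) HMOX1, heme oxygenase, fell 2.01-fold, and 2 of 15 were lower adjusted over the list alone, with GCLM at -0.74 ± 0.14 and NQO1 at -0.63 ± 0.16. In the ATF4 list (camera adjusted p = 0.998) NUPR1, a stress-induced chromatin protein not well above background at 0 h, rose at least 1.45-fold (adjusted p = 0.0857 with a prior that follows the level and resists outliers, in a range of 0.0302 to 0.238 over all alternatives), and 5 of 21 were higher and 3 lower adjusted over the list alone, with ATF3 at 0.65 ± 0.10 and the amino acid transporter SLC7A5 at -0.84 ± 0.14. The median of that list was -0.07, its mean 0.04, and the direction given by camera was higher.

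Of 25 apoptosis genes, BID, a pro-apoptotic BH3 protein, fell by 0.88 ± 0.11 on the log2 scale and 24 did not pass (camera adjusted p = 0.958; 2 higher and 3 lower adjusted over the list alone), with PMAIP1 above and BAD at 0.72 ± 0.14. With the mean of its probes, BID stood at -0.43 (adjusted p = 0.0785, in a range of 4e-04 to 0.238 over all alternatives), which did not pass. The NF-kB list had 0 of 8 passing over all genes or adjusted over the list alone (camera adjusted p = 0.958, direction higher, median 0.04, mean -0.07), with NFKB2 at -0.58 ± 0.18, RELB at -0.37 ± 0.15 and CCL2 at 0.29 ± 0.14.

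The core pluripotency factors POU5F1 (0.22 ± 0.13, adjusted p = 0.309), NANOG (0.31 ± 0.13, adjusted p = 0.2) and SOX2 (-0.12 ± 0.14, adjusted p = 0.629) did not pass the test. In the pluripotency list 0 of 23 passed (camera adjusted p = 0.652; 2 higher and 2 lower adjusted over the list alone). The de novo methyltransferase DNMT3B stood at -0.72 ± 0.11 (adjusted p = 0.051), UTF1 at 0.76 ± 0.12 (adjusted p = 0.0516) and DPPA2 at 0.71 ± 0.12 (adjusted p = 0.0547).

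Most markers of differentiated lineages were not above background on 2 arrays, with 13 of 22 neurectoderm, 20 of 22 mesoderm, 7 of 15 endoderm and 10 of 13 trophoblast markers untested for that reason. Of the rest, 0 passed over all genes. The neurectoderm list had 3 of 9 higher adjusted over the list alone (camera adjusted p = 0.507, direction higher, median -0.01, mean 0.15), with SOX3 at 0.89 ± 0.15, the cadherin CDH2 at 0.57 ± 0.11 and TUBB3 at 0.56 ± 0.14. The endoderm list had 0 of 8 adjusted over the list alone (camera adjusted p = 0.773), with APOA2, detected on 1 of the 2 arrays at 0 h, at 0.47 ± 0.27 and AFP at -0.29 ± 0.18. TTR, not well above background at 0 h, did not pass (limma adjusted p = 0.129), with a bound of 1.09-fold higher. The mesoderm and trophoblast lists were too small for a list test and had 1 higher and 1 lower each adjusted over the list alone, with KDR at 0.81 ± 0.16, EOMES, detected on 1 of the 2 arrays at 24 h, at -0.92 ± 0.22, and KRT7, detected on 1 of the 2 arrays at 0 h, at 0.63 ± 0.30. PGF, not well above background at 0 h, did not pass (limma adjusted p = 0.0624), with a bound of 1.68-fold higher. VGLL1, not well above background at 24 h, did not pass (limma adjusted p = 0.0911), with a bound of 1.09-fold lower.

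**Figure D2:**
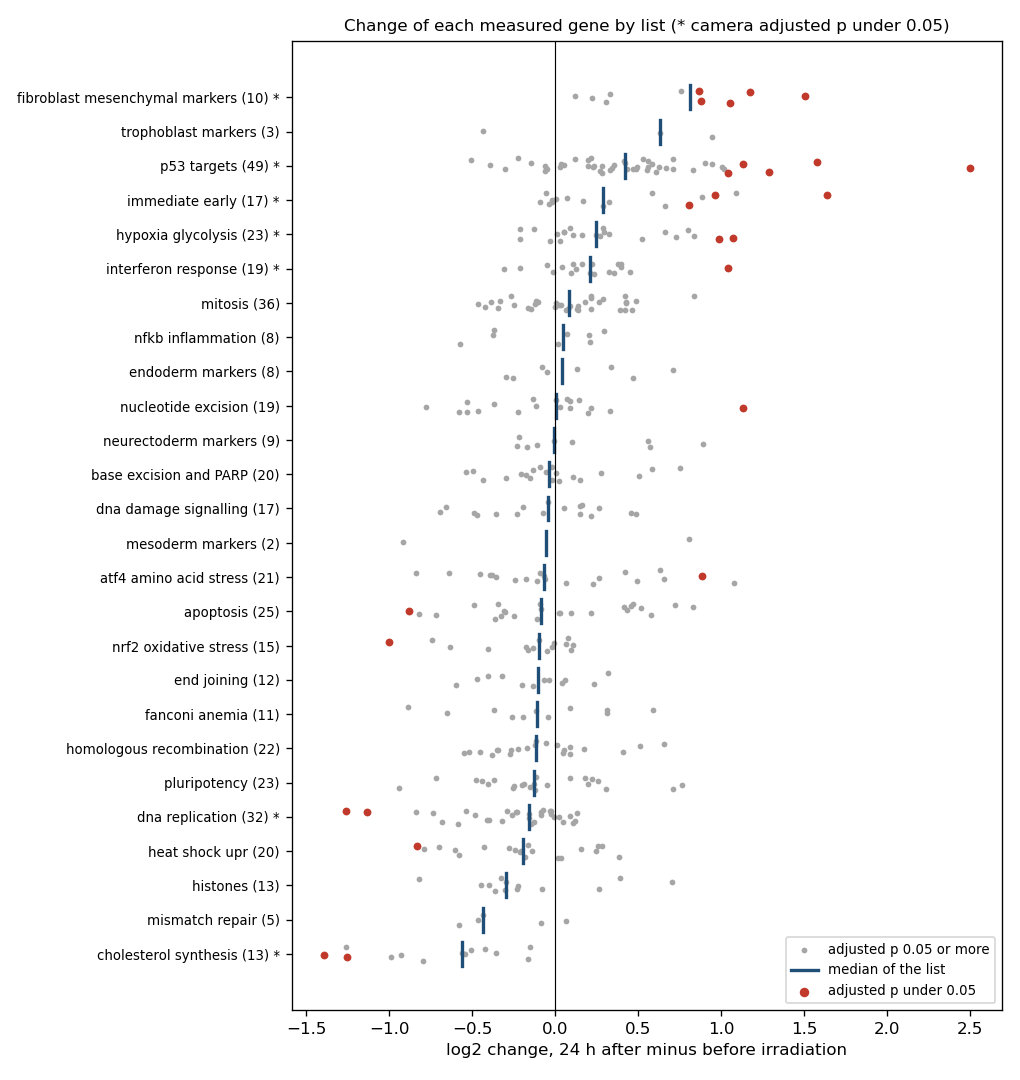
Log2 change from 0 h to 24 h (x axis) of every measured member of each gene list (y axis, number of members in brackets); red points passed adjusted p of 0.05, bars are list medians and stars mark lists called by camera. All 13 cholesterol synthesis genes lie below 0, all 10 fibroblast and mesenchymal markers lie above 0, and 41 of 49 p53 targets lie above 0.

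Camera called 7 of 24 lists, 5 higher and 2 lower. None of the 7 passed with an estimated correlation (smallest adjusted p = 0.44, 2 lists at an unadjusted p under 0.05). That test rests here on 2 degrees of freedom and could rarely pass, so it does not decide whether correlation between genes made the shifts. Fry called 3 of the 7, the p53 targets, DNA replication, and the fibroblast and mesenchymal markers. Without an unirradiated sample at 24 h, the values compare time points around irradiation and do not separate it from a day in culture.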

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

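Probes without a single gene name entered no gene test. Here detected means a detection p under 0.01, and not detected a detection p of 0.05 or more. Of 20859 such probes, 17 were detected on both 24 h arrays and not detected on either 0 h array. This put the signal forward for a closer look. The reverse held for 34 probes, detected on both 0 h arrays and not detected on either 24 h array by the same limits. Of the 6126 such probes kept by the detection filter, limma called 0 in a fit of every kept probe (as it did over all 20361) and 1434 had an unadjusted p under 0.05. Groups of 2 arrays are too small for a test of outlying samples.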

How the results depend on the processing

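Gene counts moved with the processing, while list counts moved little except with the list test itself. Against 251 called genes, limma called 1641 with a normexp background and offset of 50 (251 shared), 2199 without background correction (247 shared), 721 with scaling to the 75th percentile (238 shared), 388 with the authors' log2 values (251 shared) and 1844 with the stricter detection filter (181 shared). The eBayes prior that follows the level and resists outliers gave 2522 (228 shared). Chosen after seeing the data, the trend alone gave 2488 and the robust prior alone 190, so the trend moved the count. In simulated data whose variance follows the level, this prior recovered 72% of genes changed by 1 on the log2 scale against 29%, with 5 against 6 false calls. Those variances were drawn from a fitted prior that follows the level, so the simulation favoured it by construction and does not vouch for the larger count. Limma called 0 genes without a detection filter (3456 at an unadjusted p under 0.05), 0 when every kept probe was tested (5235 at that p) and 0 with any array left out (lowest and highest 0; 1831, 2040, 3341 and 2557 at that p without 0 h replicate 1, 0 h replicate 2, 24 h replicate 1 and 24 h replicate 2). A lone array was then assumed to vary like the other group. The labels do not say that replicate numbers pair the samples, and replicates with the same number shared little (correlation of deviations across genes 0.154); a replicate block gave 0 genes (3828 at that p) and 7 lists. The mean of a gene's probes gave 336, and a minimum of 1.5-fold 251. Beyond the trend, the cause was not tested.

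Camera called 6 to 9 lists against 7 under the other settings and with arrays left out. With an estimated correlation it called 0, and fry called 3. The heat shock list passed under 4 settings (adjusted p 0.0181 to 0.0472 there, up to 0.57 elsewhere) and the NRF2 list without a detection filter (0.0407, up to 0.752 elsewhere).

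Of 34 named genes that were called, 14 had folds over 1.5 times smaller without background correction, 8 with offset 50 and 1, ANGPTL4, with the mean of probes; all these stayed called, and background left in the signal shrinks folds by construction. Named genes that missed the threshold in the main fit gained a call under other settings. These were 35 with offset 50, 38 without background correction, 40 with the stricter filter and 36 with the trend and robust prior. BID lost its call with the mean of probes (0.0785), NUPR1 with the trend and robust prior (0.0857) and with the trend alone (0.086), and JAKMIP2 (0.0537), JUN and RRM2 (0.0504 each) with the robust prior alone. Their adjusted p reached 0.238 over all alternatives.

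Of the named genes, H2BC5 reversed, to -0.014 with the mean of its probes. The 7 lists whose side relative to other genes flipped were called under no setting (median log2 changes follow). Apoptosis stood at -0.066 with offset 50, -0.049 without background correction, -0.038 with percentile scaling, -0.026 with the stricter filter, -0.084 with the trend and robust prior and -0.132 to -0.027 with arrays left out. ATF4 stood at -0.066 with offset 50 and the authors' values, -0.064 without background correction, -0.093 with no filter and the stricter filter, -0.068 with the trend and robust prior and -0.139 to 0.056 with arrays left out. Base excision stood at -0.039 with the mean of probes, and nucleotide excision at 0.049 with the stricter filter. With arrays left out, base excision ranged from -0.098 to 0.058, endoderm from 0.019 to 0.17, NF-kB from -0.074 to 0.115 and pluripotency from -0.226 to 0.034. The cause was not tested. The 24 h arrays had less signal over background (69.7 and 60.4 against 82 and 83.1), which limits dim genes most.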

Other observations

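Tests of mixed-in fibroblasts, of a few genes carrying the p53 list, of array brightness and of time in culture, as well as the family tests, were chosen after the results were seen. The tests of further probes and of serum response factor and YAP targets were devised after the gene and list results they bear on, before their own values were seen.

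Genes named in this paragraph were picked from the called genes after their values were seen, so they stand for no group, and no list of their functions was tested. Each was called at adjusted p of 0.0447 to 0.0499 in limma. The integrin subunits ITGA5 (log2 change 1.33 ± 0.13 SE) and ITGA3 (1.02 ± 0.10), the matricellular proteins CCN1 (1.13 ± 0.12) and CCN2 (0.80 ± 0.10), the plasminogen activator PLAU (1.04 ± 0.12), the actins ACTG2 (1.00 ± 0.13) and ACTA1 (0.85 ± 0.10), and the lamin gene LMNA (0.88 ± 0.12) rose. The dynein docking factor ODAD3 (1.504 ± 0.125) and the BBSome subunit BBS9 (1.55 ± 0.15) rose, and WDR35, of intraflagellar transport, fell (-1.17 ± 0.10). The transcription factor SREBF1 (-0.92 ± 0.12), its regulator SPRING1 (-1.06 ± 0.12) and the acyltransferase GPAM (-0.95 ± 0.12) fell. The splicing kinases CLK1 (-0.81 ± 0.11) and CLK4 (-0.96 ± 0.13), the splicing factor SRSF2 (-0.78 ± 0.10) and the paraspeckle proteins PSPC1 (-1.20 ± 0.10) and RBM14 (-1.44 ± 0.13) fell.

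Families that share the letters of their symbol were tested with camera, also after the data were seen, over 133 families of at least 10 genes. At a preset correlation 11 passed. With an estimated correlation, a test of little power here, 0 passed and 0 had an unadjusted p under 0.05. The DDX family of RNA helicases was lower (28 of 33 below 0, median -0.21, adjusted p = 0.026; adjusted p = 0.952 with an estimated correlation), as were the TAF family, mostly subunits of TFIID (15 of 18 below 0, median -0.33, adjusted p = 0.026; 0.952 with an estimated correlation), and the RBM family of RNA-binding proteins (21 of 30 below 0, median -0.36, adjusted p = 0.0381; 0.952 with an estimated correlation). The HLA family of antigen presentation was higher (15 of 18 above 0, median 0.30, adjusted p = 0.0281; 0.952 with an estimated correlation), with 2 of its members also in the fixed lists and probes that similar HLA genes may share. Directions were the same under the 3 other scalings, and with an array left out the largest adjusted p was 0.0625 for DDX, 0.0676 for TAF, 0.102 for RBM and 0.167 for HLA.

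Called genes could reflect single probes that misreport their gene. A further kept probe was on the array for 55 of the 251 called genes. Over all 2634 genes with such a probe, 70.6% had the same sign. Called genes were chosen for large changes, so the contrast with that share decides little. In 52 of the 55 (94.5%, exact 95% interval 84.9% to 98.9%, genes taken as independent) the sign was the same. The median change of the further probe was 73.7% of the first. These values argue against misreporting for most of the 55. The exceptions were CSTF3 (-1.13 against 0.51), NFS1 (1.09 against -0.56) and EPHA8, which was not well above background at 0 h. The lower brightness of the 24 h arrays may also have added to the calls: with scaling to the 75th percentile, 294 of 438 dimmer called genes were higher against 65 of 283 brighter ones, a difference of 44.2 percentage points (95% interval 37.6 to 50.7). Quantile normalization evens out such a lean by level (-7 percentage points there, 95% interval -19.6 to 5.7), whatever its source, and brightness and position on the slide, which went with the group, stay open. The intervals of both differences take called genes as independent. All genes share the same few arrays, so an effect of an array can reach many of them at once. These intervals therefore do not measure how much such a lean varies between arrays.

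The p53 target list could have been carried by a few strongly changed members. The lower quartile of its 49 members was 0.194, against -0.249 over all genes, and the 44 members that were not called had a median of 0.35. With 41 of the 49 already known to lie above 0, a lower quartile above 0 was fixed beforehand. The values therefore restate the list result, a shift spread over many members, and are no separate test. Whether the shift came from irradiation or from a day in culture cannot be told apart, because 0 arrays held unirradiated cells at 24 h, and the same holds for the cholesterol, hypoxia and immediate early lists.

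The rise of fibroblast and mesenchymal markers could come from human fibroblasts mixed into the 24 h samples. Of 9 matrix and mesenchymal transcripts of such cells (COL3A1, LUM, DCN, POSTN, FBN1, MMP2, LOX, PRRX1 and TWIST1), 0 were detected on both 24 h arrays. These were the 9 named members of the list that the detection filter had left untested, so that outcome was fixed beforehand and tests nothing. All lay near background and most were detected on no array here. Human fibroblasts mixed into those samples stay open. As a hypothesis, actin and adhesion genes driven by serum response factor and YAP may have risen in the stem cells themselves. A list of such targets outside the tested list was higher (16 of 19 above 0, median 0.16, unadjusted camera p = 0.0356, and 0.347 with an estimated correlation). Of its members 0 were called, with AXL nearest (0.67 ± 0.11, adjusted p = 0.0525 in limma) and AMOTL2 on the other side (-0.71 ± 0.24). The list did not hold the called genes CCN1, CCN2, ACTG2 and ACTA1 named above, so its count of calls describes these 19 alone. Other mesenchymal or differentiating cells, time in culture and cell density stay open, as untested.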
